A study of Homo sapiens with 4 samples.

How the data were processed

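Bulk RNA-seq was made from total RNA of C28/I2 cells grown with 10% serum and 1% antibiotics, with Trizol extraction and an in-house library kit of the sequencing company, per the labels. Groups come from the treatment label of each sample: 2 libraries with 25 ng/mL FABP4 for 48 h and 2 with 0.5% DMSO for 48 h. No label says whether the FABP4 cells also received DMSO, and no test of the vehicle was made. RNA selection and strandedness are not given in the sources used here.

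The table deposited by the authors holds FPKM values (fragments per kilobase of transcript, scaled to library size) for each library, per the file headers. It also holds the authors' log2 fold change, p-value and q-value from DESeq2, per the file headers. A positive log2 fold change of the authors means higher with FABP4, as judged from the deposited FPKM; 1196 genes have no q-value. Bowtie2 2.2.5, RSEM 1.2.12, DESeq2 1.4.5 and the build GRCh38.p13 are named without their roles, per the submitters' processing notes. The annotation and filters are not given in the sources used here.

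The design had assumed counts, with a stated fallback for FPKM; since the file holds FPKM, the fallback was used. Values were taken as log2(FPKM + 1), and genes with at least 1 FPKM in at least 2 libraries were kept (12490 of 19215). limma 3.58.1 in R 4.3.3 was fitted to the condition alone, with variance moderation along the mean, a two-sided test and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(FPKM + 1) scale and understate the change of low genes. The test was tested on simulated data with the real means (10 runs of 12490 genes, 200 of them changed). Their noise was normal and independent between genes, with a spread drawn from the trend that limma had fitted. It recovered 88.5% of genes changed by a log2 fold of 1 and 22.1% of those changed by 0.5, with 4.90% of calls false, and made 0 calls where nothing was changed. Such data obey the assumptions of the test, so these figures do not give its error rate in the real libraries.

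The 26 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except those the closing section names. The 22 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation, where none passed. The estimated setting is stricter in itself, as it rests on the 2 residual degrees of freedom of 4 libraries. For the TGF-beta list the estimate was -0.036, below the preset, yet the unadjusted camera p rose from 0.0021 to 0.077. For that list the loss thus does not point to correlation between members. In the other lists that passed, the estimate lay above the preset, from 0.036 (endoplasmic reticulum stress) to 0.27 (interferon). It was 0.23 for NRF2 targets, 0.16 for cell cycle genes and 0.10 for matrix genes. There the loss may come from correlation, from the few degrees of freedom or from both. The rotation test fry of limma was planned as a description of the lists. For the 8 lists that camera passed it gave unadjusted p values from 0.064 (TGF-beta) to 0.34 (cell cycle). None of these was under 0.05. The interferon list holds 2 names of 1 gene. Named are FABP4; the 12 called genes with the largest log2 fold change in each direction that have a mean of at least 1 FPKM, groups that do not overlap and a protein-coding style symbol; for each list at most 4 called members, or else the 2 with the smallest p; and 14 genes of cartilage, protease, inflammation and fatty acid biology. Members that pass when adjusted over the list alone are named besides. AGR2, S100P and CT47A2, and FOSL1 and EGR1 with their levels, were chosen after their values were seen.

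Depth was estimated from the low FPKM of single-exon genes. With whole fragments these are multiples of what 1 fragment is worth at the gene's length less the mean fragment length, fitted at 280 bases. Of 417 such genes considered, 76, 90, 96 and 89 had usable values in FABP4 replicates 1 and 2 and DMSO replicates 1 and 2. The 95% bootstrap ranges were 12075000 to 12400000 fragments for FABP4 replicate 1, 11125000 to 11400000 for FABP4 replicate 2, 12650000 to 12875000 for DMSO replicate 1 and 12950000 to 13175000 for DMSO replicate 2. In data simulated with whole fragments and the same length formula, the largest error over 20 libraries was 0.743%. The deposited FPKM need not come from whole fragments, so this error does not give the accuracy in the real libraries. At the estimated depths, 1 FPKM of a transcript with an effective length of 1 kilobase rests on 11.3 to 13.1 fragments. Levels near 1 FPKM thus carry a large counting error. Coordinates are those of GENCODE 29 on GRCh38. None of 10 housekeeping genes was at 0 in a library.

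To mark genes with shared sequence, 60 windows of 50 bases along the longest GENCODE 29 transcript of each gene were looked up in the transcripts of all other genes. Of 19215 genes 18774 had a transcript, and genes with at least 50% of windows found elsewhere are called uncertain: 12 of the 68 called genes with a transcript. ZASP, ABCF2-H2BE1 and 4 other called genes had none. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The alternatives were the replicate number as a block, other scalings of the FPKM, no filter and a stricter one, a pseudocount of 0.1, robust variance moderation, a log2 fold change of at least 1, an adjusted p of 0.1, and each library left out in turn. Groups of 2 allow neither an outlier test nor regrouping of the samples.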

Results

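C28/I2, an immortalised human chondrocyte line, was kept for 48 h either with 25 ng/mL of FABP4, the adipocyte fatty acid-binding protein that fat cells release as an adipokine, or with 0.5% DMSO. The comparison asks which transcripts differ between cells given this protein and control cells. Each condition has 2 RNA-seq libraries, and every level below is a mean FPKM ± SD over n = 2 libraries, FABP4 first and DMSO second. The authors' table lists 19215 genes, of which 12490 reached 1 FPKM in at least 2 libraries and were tested, and 1337 were listed at 0 in all 4. The estimated depth was 12250000 and 11275000 fragments for FABP4 replicates 1 and 2, and 12750000 and 13050000 for DMSO replicates 1 and 2. Across the tested genes, which are not independent replicates, log2 levels correlated with a Pearson r of 0.994 between the FABP4 libraries, 0.993 between the DMSO libraries and 0.991 to 0.993 between conditions. No source used here says that the replicates came from separate cultures, and the p-values measure only the spread between these samples.

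Cells given FABP4 had more mRNA of FOS, a subunit of the AP-1 transcription factor, and less of NPPB, FGF1, F3, IL24 and EDN1. FOS stood at 28.4 ± 0.636 against 8.90 ± 1.83 FPKM, 3.19 times the control level. The genes of a natriuretic peptide (NPPB), a fibroblast growth factor (FGF1), tissue factor (F3), a cytokine (IL24) and endothelin (EDN1) stood at 0.441 to 0.548 times theirs. In limma, 74 of 12490 genes passed an adjusted p of 0.05, 37 higher and 37 lower, and 1209 had an unadjusted p under 0.05. In all 74 both FABP4 libraries lay beyond both DMSO libraries, as in 36.9% of the tested genes, where chance gives 33.3%. With the FPKM rescaled to equal totals 180 genes passed (65 higher, 115 lower), and without the filter on low values none did in limma (1362 at an unadjusted p under 0.05). Leaving out 1 library gave 150 calls without FABP4 replicate 1, 98 without FABP4 replicate 2, 123 without DMSO replicate 1 and 49 without DMSO replicate 2, of which 60, 45, 55 and 31 were among the 74.

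Among the 12 called genes with the largest rise, FOS (gene ID 2353, chromosome 14, 75278774 to 75282230, GRCh38) had the smallest adjusted p (log2 fold change 1.58, SE 0.13, limma adjusted p = 1.25e-05). PNRC1, a nuclear receptor coactivator gene, rose to 1.87 times the control level, at 20.8 ± 0.325 against 11.1 ± 1.04 FPKM (log2 fold change 0.85, SE 0.12, limma adjusted p = 0.00414). ZASP (gene ID 101927655) rose to 18.9 ± 1.84 against 8.14 ± 1.75 FPKM (log2 fold change 1.13, limma adjusted p = 0.00118). The authors' deposited table does not call it, with a log2 fold change of 1.78 and an unadjusted DESeq2 p of 0.404 (q = 0.998). For 5 of the 12 genes the higher FABP4 value lay well apart, in replicate 2. GPX2, a glutathione peroxidase gene, had 1.01 and 5.21 FPKM in FABP4 replicates 1 and 2 against 0 and 0.36 in DMSO replicates 1 and 2 (log2 fold change 1.60, limma adjusted p = 0.0307). Its log2 fold change was 0.79 without FABP4 replicate 2 and 2.41 without FABP4 replicate 1. The GPX2 call was lost in 6 of 13 alternatives, with a limma adjusted p of up to 0.768. These were median-of-ratios scaling, no filter, robust variance moderation, quantile normalization, and DMSO replicate 1 or 2 left out. The aldo-keto reductase genes AKR1C3 and AKR1C2 had 7.61 and 13.71 FPKM against 4.91 ± 0.134 (log2 fold change 0.93, limma adjusted p = 0.0220), and 1.48 and 2.77 against 0.700 ± 0.170 (log2 fold change 0.85, limma adjusted p = 0.0431). The AKR1C3 call was lost without FABP4 replicate 2 (limma adjusted p = 0.188) or DMSO replicate 2 (limma adjusted p = 0.0797), in a range of 3.58e-09 to 0.595 over its alternatives. The AKR1C2 call was lost in 7 of 12 alternatives, with a limma adjusted p of up to 0.591. These were the replicate block, median-of-ratios scaling, no filter, a pseudocount of 0.1, quantile normalization, and FABP4 replicate 2 or DMSO replicate 2 left out. Without FABP4 replicate 2 their log2 fold changes were 0.54 and 0.55. MDK, the gene of the heparin-binding growth factor midkine, had 14.66 and 22.94 against 9.23 ± 2.59 (log2 fold change 0.94, limma adjusted p = 0.0213), a call lost without DMSO replicate 2 (limma adjusted p = 0.146), in a range of 7.73e-09 to 0.595 over its alternatives. The sulfotransferase gene SULT1A4 had 19.01 and 30.83 against 10.5 ± 1.39 (log2 fold change 1.14, limma adjusted p = 0.00558). Its call was lost without the filter on low values, with robust variance moderation and after quantile normalization (limma adjusted p = 9.13e-13 to 0.591 over its alternatives).

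The other 4 genes of that group are low or share sequence with other genes. FABP6, an ileal bile acid-binding relative of FABP4, had 1.76 ± 0.205 FPKM with FABP4 against 0 and 0.7 in DMSO replicates 1 and 2 (log2 fold change 1.08, limma adjusted p = 0.0200). Its log2 fold change was 0.69 without DMSO replicate 1, and the call was lost without DMSO replicate 1 (limma adjusted p = 0.102), in a range of 6.58e-07 to 0.591 over its alternatives. P2RY11, an ATP receptor gene within a readthrough transcript with PPAN, had 6.99 ± 0.163 against 4.12 and 0.87 (log2 fold change 1.37, limma adjusted p = 0.0307). Its log2 fold change was 2.09 without DMSO replicate 1 and 0.64 without DMSO replicate 2. The P2RY11 call was lost in 5 of 12 alternatives: median-of-ratios scaling, no filter, a pseudocount of 0.1, robust variance moderation and quantile normalization (limma adjusted p = 2.53e-13 to 0.769 over its alternatives). TP53TG3B had 2.17 and 1.56 against 0 and 0.53 (limma adjusted p = 0.00764), a call lost without the filter and after quantile normalization (limma adjusted p = 8.64e-09 to 0.552 over its alternatives). TBC1D3C had 7.82 ± 0.940 against 4.08 ± 1.00 FPKM (log2 fold change 0.81, limma adjusted p = 0.0148), a call lost without DMSO replicate 2 (limma adjusted p = 0.0853), in a range of 2.27e-04 to 0.591 over its alternatives. Of 50-base windows along the longest transcript, 100% in TP53TG3B, 96.7% in TBC1D3C, 98.3% in SULT1A4, 60% in P2RY11 and 53.3% in AKR1C2 also occur in another gene, so the levels of these 5 genes are uncertain.

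Among the 12 called genes with the largest fall, the lowest log2 fold changes were those of ABCF2-H2BE1 (-1.66), a readthrough, and of the keratin-associated protein gene KRTAP2-3 (-1.01). KRTAP2-3 had 6.87 ± 2.02 against 14.7 ± 2.89 FPKM (limma adjusted p = 0.00762). NPPB (gene ID 4879, chromosome 1, 11857464 to 11858931, GRCh38), the B-type natriuretic peptide gene, fell to 15.2 ± 0.919 against 30.3 ± 1.27 FPKM (log2 fold change -0.95, SE 0.12, limma adjusted p = 0.00118). F3 (gene ID 2152, chromosome 1, 94529225 to 94541800, GRCh38), the tissue factor gene that starts coagulation, fell to 32.03 ± 1.77 against 61.5 ± 8.64 FPKM (log2 fold change -0.91, SE 0.13, limma adjusted p = 0.00414). FGF1 (gene ID 2246, chromosome 5, 142592178 to 142698070, GRCh38), the acidic fibroblast growth factor gene, fell to 2.43 ± 0.0990 against 5.51 ± 0.587 FPKM (log2 fold change -0.92, SE 0.13, limma adjusted p = 0.00454). EDN1 had 10.4 ± 1.04 against 18.9 ± 1.71 FPKM (log2 fold change -0.81, limma adjusted p = 0.00590) and IL24 4.93 ± 0.0424 against 9.78 ± 1.92 FPKM (log2 fold change -0.85, limma adjusted p = 0.00762). SEMA7A, a membrane-anchored semaphorin gene, had 19.0 ± 2.67 against 34.4 ± 0.0778 FPKM (log2 fold change -0.83, limma adjusted p = 0.00558). HSD17B6, a hydroxysteroid dehydrogenase gene, had 4.09 ± 0.750 against 8.53 ± 1.14 FPKM and ACTG2, a smooth muscle actin gene, 8.75 ± 1.09 against 15.7 ± 2.01 FPKM (limma adjusted p = 0.00590 and 0.0103). The calls of KRTAP2-3, SEMA7A and ACTG2 were lost without the filter and after quantile normalization (limma adjusted p = 2.17e-09 to 0.591, 7.51e-08 to 0.471 and 1.10e-05 to 0.532 over their alternatives).

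For 3 of these 12 genes the level is uncertain, from shared sequence or readthrough. CT47A5, of a cancer/testis family, had 6.86 ± 0.311 against 14.4 ± 5.29 FPKM (limma adjusted p = 0.0174) and shared 100% of its windows, while CT47A2 of the same family was called higher. Its log2 fold change of -0.92 became -0.57 without DMSO replicate 1, and its call was lost without the filter, with robust variance moderation and after quantile normalization (limma adjusted p = 9.35e-08 to 0.591 over its alternatives). TMED7-TICAM2 had 2.67 ± 0.354 against 5.42 ± 1.48 FPKM (limma adjusted p = 0.0253) and shared 96.7%. Its call was lost without DMSO replicate 2 (limma adjusted p = 0.175), in a range of 1.19e-04 to 0.591 over its alternatives. ABCF2-H2BE1, a readthrough of 2 genes, had 0 and 0.88 FPKM against 2.01 and 5.22 (log2 fold change -1.66, limma adjusted p = 0.0111). That call was lost without DMSO replicate 2 (limma adjusted p = 0.105), in a range of 3.03e-19 to 0.677 over its alternatives.

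**Figure D1:**
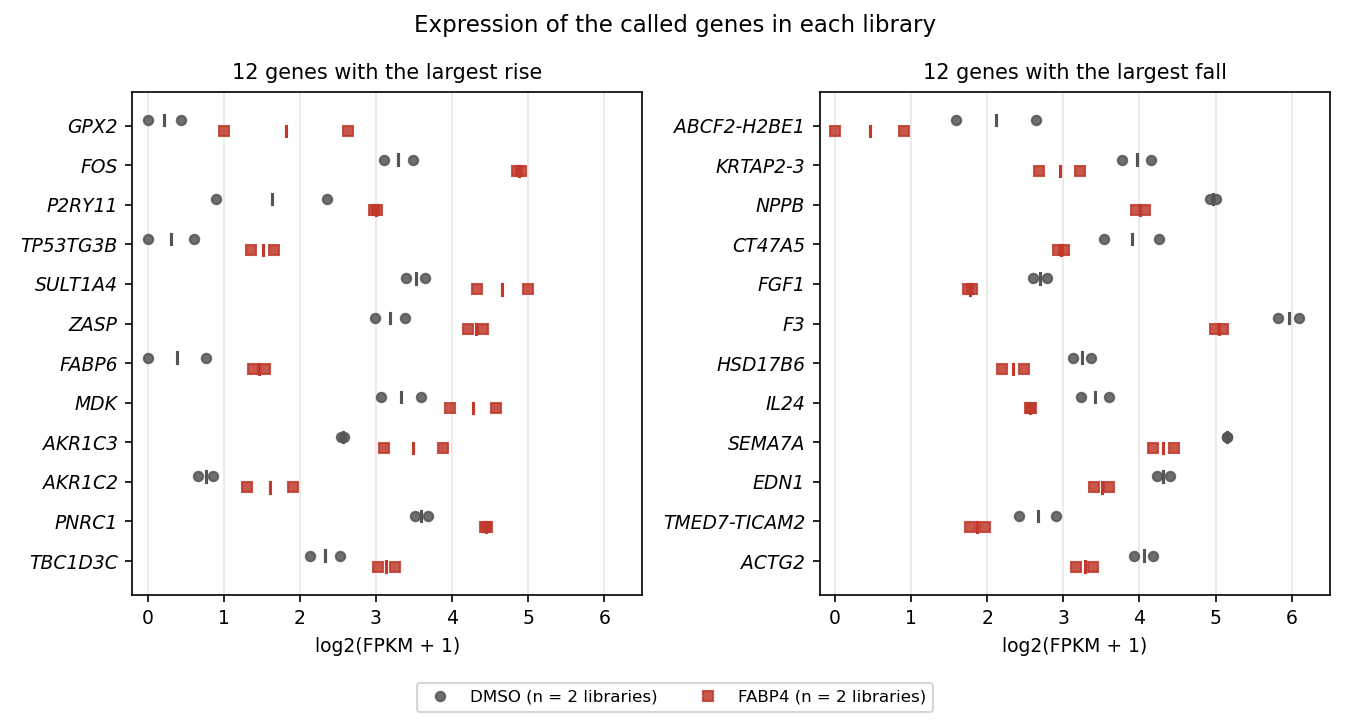
Level in every library, as log2(FPKM + 1), of the 12 called genes with the largest rise (left) and the 12 with the largest fall (right): circles are DMSO libraries, squares FABP4 libraries and short lines the group means. The groups do not overlap for any of these genes, and the FABP4 squares lie farthest apart for GPX2, with 1.01 and 5.21 FPKM.

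The cells' own FABP4 transcript (gene ID 2167, chromosome 8, 81478419 to 81483263, GRCh38) was near the detection filter and fell in cells given the protein, at 0.795 ± 0.332 against 2.02 ± 0.120 FPKM (log2 fold change -0.76, SE 0.16, limma adjusted p = 0.0377). The call was lost in 6 of 13 alternatives, among them without FABP4 replicate 2 (limma adjusted p = 0.212), DMSO replicate 1 (limma adjusted p = 0.129) or DMSO replicate 2 (limma adjusted p = 0.113), in a range of 6.26e-04 to 0.564 over its alternatives. The authors' deposited table gives it a q of 0.889. Of 14 cartilage, protease, inflammation and fatty acid genes fixed in advance, 9 could be tested, and none passed in limma (1 at an unadjusted p under 0.05). The aggrecan gene ACAN stood at 3.11 ± 0.820 against 3.09 ± 0.290 FPKM (log2 fold change -0.0039, limma adjusted p = 0.998) and the transcription factor gene SOX9 at 9.40 ± 0.827 against 11.3 ± 0.0354 FPKM (log2 fold change -0.25, limma adjusted p = 0.531). The collagenase and stromelysin genes had 24.3 ± 2.17 against 25.0 ± 0.304 FPKM (MMP1), 531 ± 9.75 against 546 ± 32.1 FPKM (MMP3) and 7.12 ± 0.750 against 5.19 ± 0.764 FPKM (MMP13), with limma adjusted p values of 0.979, 0.986 and 0.240. The receptor genes TLR4 and CD36 had 3.16 ± 0 against 3.80 ± 0.502 FPKM and 1.29 ± 0.304 against 1.495 ± 0.346 FPKM, with limma adjusted p values of 0.731 and 0.929. PPARG had 13.02 ± 0.0849 against 12.7 ± 1.07 FPKM and FABP5 39.0 ± 7.09 against 40.9 ± 4.96 FPKM, with limma adjusted p values of 0.983 and 0.954. COL2A1, ADAMTS4, ADAMTS5, IL6 and PTGS2 stayed under 1 FPKM in every library. Among them IL6 had 0.505 ± 0.276 against 0.630 ± 0.509 FPKM and PTGS2 0.385 ± 0.431 against 0.1 ± 0.0424 FPKM.

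CCN2, LTBP2 and ACTA2 were the called members of the TGF-beta and BMP response and fibroblast-like matrix lists. Of 23 tested TGF-beta and BMP response genes 2 fell: CCN2, the connective tissue growth factor gene, had 25.7 ± 0.474 against 43.9 ± 5.36 FPKM (log2 fold change -0.75, SE 0.12, limma adjusted p = 0.00949) and LTBP2, a latent TGF-beta binding protein gene, 2.27 ± 0.0283 against 3.98 ± 0.0566 FPKM (log2 fold change -0.61, limma adjusted p = 0.0433). The CCN2 call was lost without DMSO replicate 2 (limma adjusted p = 0.0766), in a range of 1.21e-06 to 0.482 over its alternatives. The LTBP2 call was lost in 8 of 14 alternatives, with a limma adjusted p of 0.0112 to 0.525 over its alternatives. These losses came with the replicate block, no filter, a pseudocount of 0.1, quantile normalization and each library left out in turn. Adjusted over the list alone, CCN2, LTBP2, TGFB2, TGFBI, INHBA and COL4A1 were lower and ID2 was higher. The 23 members went both ways, 11 above 0 and 12 below, with a median log2 fold change of -0.011 and a mean of -0.11. Of 17 fibroblast-like matrix genes 1 fell, the smooth muscle actin gene ACTA2, at 39.9 ± 3.20 against 60.8 ± 0.0566 FPKM (log2 fold change -0.60, SE 0.12, limma adjusted p = 0.0296). Its call was lost without FABP4 replicate 2 (limma adjusted p = 0.112), DMSO replicate 1 (limma adjusted p = 0.0827) or DMSO replicate 2 (limma adjusted p = 0.117), in a range of 1.77e-04 to 0.482 over its alternatives. Adjusted over the list alone ACTA2, TAGLN and LOX were lower, and 13 of the 17 members lay below 0, with a median of -0.051.

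In limma's camera test both lists, with CCN2, LTBP2 and ACTA2 among their members, passed downward at the preset correlation but not with an estimated one, with an adjusted p of 0.00571 for TGF-beta and 0.00400 for matrix genes, and an adjusted p of 0.543 for each with an estimated correlation. The TGF-beta list did not pass without FABP4 replicate 1 (camera adjusted p = 0.0932), in a range of 9.30e-04 to 0.543 over its alternatives, and its median, where CCN2 and LTBP2 are members, was -0.088 to 0.0032 with a library left out. The matrix list, with ACTA2, did not pass without FABP4 replicate 1 (camera adjusted p = 0.501) or DMSO replicate 1 (camera adjusted p = 0.0589), in a range of 9.21e-07 to 0.543 over its alternatives, and its median was -0.22 to 0.068. The medians above 0 came without DMSO replicate 2 for the TGF-beta list and without FABP4 replicate 1 for the matrix list. The matrix list's mean deviation from each gene's mean was -0.16 and 0.024 in FABP4 replicates 1 and 2. In DMSO replicates 1 and 2 it was 0.073 and 0.061, so the FABP4 libraries lay farther from each other than FABP4 replicate 2 from DMSO.

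Immediate early and MAPK feedback genes moved apart. FOS rose while ETV5, an ETS factor gene induced by MAPK signalling, fell to 4.08 ± 0.516 against 6.58 ± 0.0636 FPKM (log2 fold change -0.58, limma adjusted p = 0.0489), and these were the only 2 of 28 members past the threshold. The ETV5 call was lost without FABP4 replicate 2 (limma adjusted p = 0.330), DMSO replicate 1 (limma adjusted p = 0.0685) or DMSO replicate 2 (limma adjusted p = 0.113), in a range of 0.0113 to 0.577 over its alternatives. Adjusted over the list alone, FOS, EGR1 and JUNB were higher and ETV5, FOSL1, DUSP5, SPRY4, HBEGF, KLF2 and IER5 were lower. FOSL1, another AP-1 subunit gene, had 125 ± 3.66 against 182 ± 0.898 FPKM (limma adjusted p = 0.0661) and EGR1 7.27 ± 1.21 against 4.60 ± 0.0354 FPKM (limma adjusted p = 0.0661). With 20 of 28 members below 0 and a median of -0.11, the list lay lower in camera (adjusted p = 0.00449; adjusted p = 0.543 with an estimated correlation). It did not pass without FABP4 replicate 1 (camera adjusted p = 0.529) or DMSO replicate 1 (camera adjusted p = 0.152), in a range of 6.31e-04 to 0.543 over its alternatives. Its median was -0.043 without FABP4 replicate 1 and -0.18 without DMSO replicate 2. The list's mean deviation from each gene's mean was -0.093 and 0.012 in FABP4 replicates 1 and 2. In DMSO replicates 1 and 2 it was 0.058 and 0.024, so FABP4 replicate 2 lay close to the DMSO libraries.

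Interferon-stimulated genes lay slightly higher, with 37 of 39 tested members above 0 and a median log2 fold change of 0.24. None passed singly in limma, with 11 at an unadjusted p under 0.05 and none at a q under 0.05 in the authors' deposited table. Adjusted over the list alone, XAF1 (4.74 ± 0.0424 against 3.04 ± 0.834 FPKM) and PSMB9 (29.8 ± 6.35 against 20.1 ± 1.53 FPKM) were higher, with limma adjusted p values over all genes of 0.136 and 0.103. The median was 0.13 without DMSO replicate 2 (camera adjusted p = 0.00737, in a range of 5.97e-11 to 0.543 over its alternatives). The camera adjusted p was 6.20e-09, and the adjusted p was 0.543 with an estimated correlation, which was 0.27 for this list. The rotation test fry gave an unadjusted p of 0.11. The NRF2 targets of oxidative stress defence also lay higher, with 25 of 28 members above 0 and a median of 0.12 (camera adjusted p = 4.93e-04; adjusted p = 0.631 with an estimated correlation). AKR1C2 and AKR1C3 rose, and AKR1C1 joined them when adjusted over the list alone. Their values were highest in FABP4 replicate 2, where the epithelial genes AGR2 and S100P also stood highest, at 1.19 and 1.36 FPKM against at most 0.12 and 0 in the other libraries. The NRF2 median was 0.25 without that library and 0.023 without FABP4 replicate 1, so the size of the shift depends on FABP4 replicate 1 (camera adjusted p = 3.28e-07 and 0.0106, in a range of 3.28e-07 to 0.631 over its alternatives).

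Lipid synthesis and endoplasmic reticulum stress genes lay lower by small amounts. Cell cycle genes were lower in the mean, but the libraries of the conditions overlapped. Of the SREBP targets in cholesterol and fatty acid synthesis, 30 of 34 lay below 0, with a median of -0.13 (camera adjusted p = 4.93e-04; adjusted p = 0.543 with an estimated correlation). None passed singly in limma, with 4 at an unadjusted p under 0.05 and 1 at a q under 0.05 in the authors' deposited table. FADS2 had 10.2 ± 1.33 against 13.6 ± 0.587 FPKM and CYP51A1 33.2 ± 2.09 against 41.9 ± 3.19 FPKM, with limma adjusted p values of 0.221 and 0.316. In the stress and amino acid response 24 of 37 members lay below 0, with a median of -0.061 (camera adjusted p = 0.00449; adjusted p = 0.543 with an estimated correlation). The glutathione-degrading enzyme gene CHAC1 fell to 7.54 ± 0.0990 against 12.1 ± 0.651 FPKM (log2 fold change -0.61, limma adjusted p = 0.0222), and SLC7A5 was also lower when adjusted over the list alone. The CHAC1 call was lost without FABP4 replicate 1 (limma adjusted p = 0.0547), FABP4 replicate 2 (limma adjusted p = 0.0532) or DMSO replicate 2 (limma adjusted p = 0.0853), in a range of 0.00251 to 0.482 over its alternatives. Of 51 cell cycle genes 39 lay below 0, with a median of -0.066 (camera adjusted p = 0.00483, or 0.648 with an estimated correlation). Their mean deviation from each gene's mean was 0.00032 and -0.070 in FABP4 replicates 1 and 2. In DMSO replicates 1 and 2 it was -0.011 and 0.081, so FABP4 replicate 1 lay above DMSO replicate 1. The cyclin D1 gene CCND1 fell to 45.7 ± 0.537 against 68.6 ± 1.04 FPKM (log2 fold change -0.58, limma adjusted p = 0.0307), a call lost without DMSO replicate 1 (limma adjusted p = 0.0838) or DMSO replicate 2 (limma adjusted p = 0.150), in a range of 2.87e-04 to 0.460 over its alternatives. The stress list did not pass without FABP4 replicate 2 (camera adjusted p = 0.0513), in a range of 0.00297 to 0.543 over its alternatives. Its median was -0.10 without FABP4 replicate 1. The cell cycle list did not pass without FABP4 replicate 2 (camera adjusted p = 0.127) or DMSO replicate 2 (camera adjusted p = 0.157), in a range of 0.00194 to 0.648 over its alternatives. Its median was -0.11 and -0.041 without FABP4 replicates 1 and 2, -0.13 without DMSO replicate 1 and -0.0039 without DMSO replicate 2.

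**Figure D2:**
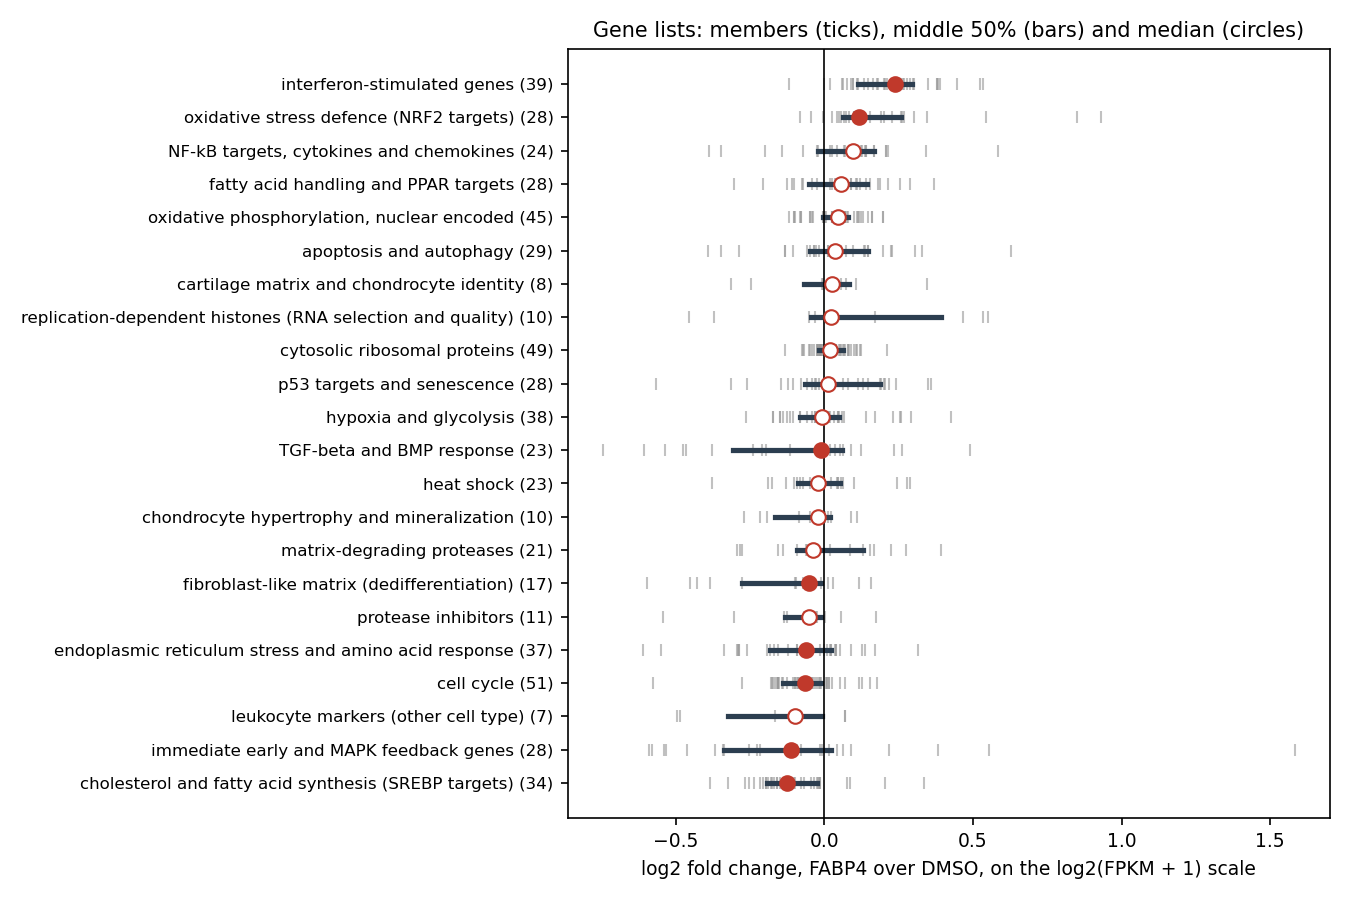
Log2 fold change (FABP4 over DMSO, on the log2(FPKM + 1) scale) of the members of the 22 gene lists with at least 5 tested genes, the number of which follows each name. Ticks are genes, bars span the middle 50% and circles the medians, filled where camera's adjusted p at the preset correlation was under 0.05; interferon-stimulated genes have the highest median, 0.24, and SREBP targets the lowest, -0.13.

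No shift was found by camera in cartilage matrix, protease or inflammation genes. The 8 tested cartilage genes had a median of 0.026 and a mean of 0.00094 while camera pointed down (adjusted p = 0.829). Of these XYLT1 had 4.48 ± 0.587 against 5.79 ± 0.113 FPKM and COL11A2 3.98 ± 0.0283 against 2.93 ± 0.205 FPKM, with limma adjusted p values of 0.384 and 0.326. Matrix-degrading proteases had a camera adjusted p of 0.718, with MMP12 at 14.6 ± 0.184 against 18.2 ± 0.566 FPKM. Protease inhibitors had one of 0.104, with TIMP3 at 66.1 ± 1.30 against 81.8 ± 1.58 FPKM. Hypertrophy genes had one of 0.370, with WNT5A at 6.54 ± 0.587 against 8.07 ± 0.424 FPKM and PTH1R at 1.07 ± 0.240 against 1.4 ± 0.212 FPKM. NF-kB targets and cytokines had one of 0.339 and a median of 0.097. Of these CCL5 had 4.64 ± 0.806 against 2.74 ± 0.0566 FPKM (limma adjusted p = 0.0658, or 0.0129 adjusted over the list alone) and LIF 5.48 ± 1.03 against 7.43 ± 0.120 FPKM.

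Fatty acid, cell death and basic metabolism lists also did not pass. Fatty acid handling and PPAR targets had a camera adjusted p of 0.458, with CEBPD at 25.1 ± 1.49 against 19.3 ± 2.86 FPKM and PPARD at 30.7 ± 1.26 against 38.2 ± 3.19 FPKM. Apoptosis and autophagy genes had one of 0.645. BMF, a BH3-only gene of that list, rose to 6.90 ± 0.778 against 4.11 ± 0.361 FPKM (log2 fold change 0.63, limma adjusted p = 0.0310), a call lost without FABP4 replicate 2 (limma adjusted p = 0.233) or DMSO replicate 2 (limma adjusted p = 0.113), in a range of 0.00708 to 0.565 over its alternatives. The p53 targets had one of 0.718, with BBC3 at 4.85 ± 0.431 against 3.59 ± 0.290 FPKM and GDF15 at 3.25 ± 0.396 against 5.29 ± 0.205 FPKM (limma adjusted p = 0.0605, or 0.0121 adjusted over the list alone). Hypoxia and glycolysis genes had one of 0.903, a median of -0.0082 and a mean of 0.0080, with ANKRD37 at 5.73 ± 1.02 against 4.04 ± 1.12 FPKM and KDM3A at 22.2 ± 1.22 against 17.9 ± 1.17 FPKM. Heat shock genes had one of 0.718, with CRYAB at 5.14 ± 0.523 against 7.06 ± 1.80 FPKM and HSPA1A at 145 ± 4.86 against 119 ± 11.8 FPKM. Oxidative phosphorylation genes had one of 0.677, with UQCRB at 16.1 ± 2.68 against 13.8 ± 0.969 FPKM and NDUFA9 at 14.6 ± 0.170 against 12.9 ± 0.184 FPKM. Ribosomal protein genes had one of 0.938, with RPL38 at 132 ± 27.9 against 112 ± 1.80 FPKM and RPL23 at 195 ± 23.7 against 179 ± 3.95 FPKM.

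Markers of other cell types and of RNA quality gave no camera call. The leukocyte list had 7 tested members and a camera adjusted p of 0.0610. Of these CSF1R had 2.24 ± 0.255 against 3.56 ± 0.156 FPKM (limma adjusted p = 0.126, or 0.0137 adjusted over the list alone) and CD3D 7 ± 3.97 against 9.52 ± 1.13 FPKM. The epithelial, endothelial and adipocyte lists had 3, 4 and 3 tested members, too few for camera, and medians of -0.13, -0.14 and 0.10. The mean was -0.15 for adipocyte markers, where FABP4 was the only call. KRT18 had 63.8 ± 2.70 against 71.9 ± 4.29 FPKM and CLDN4 2.45 ± 0.643 against 2.74 ± 0.255 FPKM. ROBO4 had 1.42 ± 0.212 against 1.80 ± 0.0495 FPKM and ESAM 6.77 ± 2.74 against 5.37 ± 1.25 FPKM. Replication-dependent histone genes had a camera adjusted p of 0.197. H2BC5 had 18.5 ± 0.742 against 12.5 ± 1.56 FPKM and H2AC6 23.7 ± 0.962 against 16.9 ± 0.0424 FPKM (limma adjusted p = 0.0599 and 0.0821), and adjusted over the list alone both and H3C10 were higher. None of 26 symbols of mitochondrially encoded genes matched the table. The MTRNR2L genes, nuclear loci that resemble mitochondrial ribosomal RNA, took 7.42% and 9.49% of the FPKM in FABP4 replicates 1 and 2 and 6.64% and 5.16% in DMSO replicates 1 and 2.

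The authors' deposited table lists 118 genes with a q under 0.05, 30 higher and 88 lower with FABP4, among 18019 genes with a q. Of these, 43 were also called by limma, all in the same direction, where independent lists would share 0.664. Both lists come from the same 4 libraries, so a large overlap was to be foreseen and is no replication. A further 31 were called by limma only and 75 in the authors' deposited table only, 6 of which were not tested here. Across the 12490 tested genes, which are not independent replicates, the log2 fold changes of both sources had a Pearson r of 0.896. In the authors' deposited table F3 has a log2 fold change of -0.90 (q = 1.30e-10), SEMA7A one of -0.90 (q = 6.64e-11) and FOS one of 1.39 (q = 0.0130). FOSL1 was called in the authors' deposited table (log2 fold change -0.53, q = 1.05e-05) and not by limma. ZASP, P2RY11, TP53TG3B and FABP6, called by limma, have a q of 0.998 each in the authors' deposited table, and ABCF2-H2BE1 one of 0.799.

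**Figure D3:**
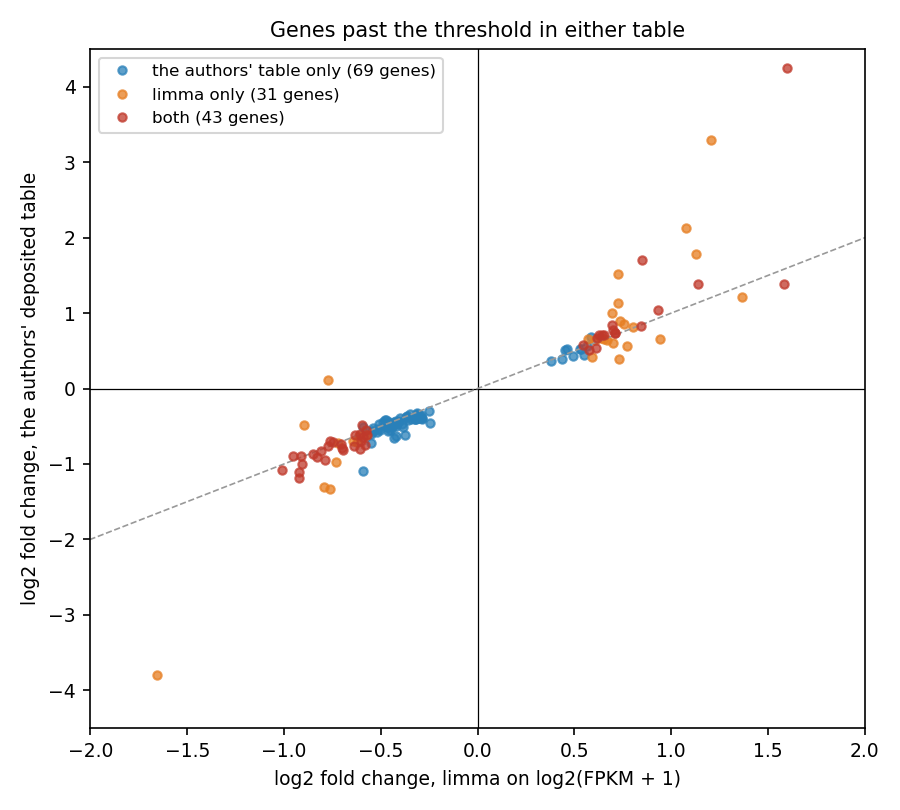
Log2 fold change (FABP4 over DMSO) of each gene past the threshold in limma on log2(FPKM + 1), horizontal axis, or in the authors' deposited table, vertical axis, among genes tested in both. The 43 genes called in both have the same sign on both axes, 31 were called by limma only and 69 in the authors' deposited table only; the dashed line marks equal values.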

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

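Quantile normalization, equal totals without the MTRNR2L genes, the crossed block and leaving out genes that share sequence were chosen after seeing the data. Against 74 called genes (37 higher, 37 lower), limma called 47 with the replicate number as a block, 180 with equal totals (65 higher, 115 lower), 0 without the filter on low values (1362 at an unadjusted p under 0.05), 116 with the stricter filter and 164 with robust moderation. It called 9 with a log2 fold change of at least 1, 147 at an adjusted p of 0.1, 10 after quantile normalization, 169 with equal totals without the MTRNR2L genes and 49 to 150 with a library left out. Median-of-ratios scaling gave 69, a pseudocount of 0.1 gave 61 and leaving out genes that share sequence 106. Of the 74 genes 46 were shared with the block, 73 with equal totals, 67 with median-of-ratios scaling and 67 with robust moderation. A higher threshold adds genes and a minimum fold removes them by construction; for the other settings the cause was not tested. The labels do not pair the replicate numbers, and deviations of same-numbered libraries correlated at -0.12 across genes; the crossed block gave 418 calls.

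The overlap with the authors' deposited table, 43 genes, became 26 with the block, 73 with equal totals, 0 without the filter, 4 with a log2 fold change of at least 1, 8 after quantile normalization, 65 with equal totals without the MTRNR2L genes and 86 with the crossed block. It became 9 with a log2 fold change of at least 1 in the authors' deposited table, and 18 to 42 with a library left out. The lower replicate correlation, 0.993, became 0.996 without the filter, 0.990 with a pseudocount of 0.1 and 0.994 without genes that share sequence. Of the 22 lists 8 passed, 6 to 10 passed under the alternatives that refit the genes, and 0 with an estimated correlation in camera (lowest adjusted p 0.543). With a library left out 7 to 9 passed, of which 5, 6, 6 and 7 were among the 8 without FABP4 replicate 1, FABP4 replicate 2, DMSO replicate 1 and DMSO replicate 2. Without FABP4 replicate 2 the lists split into 5 higher and 4 lower, against 2 higher and 6 lower with all libraries. The cause was not tested.

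Over 82 results for named genes and passing lists, 958 values kept direction and side of the threshold, 127 kept direction and no longer passed, 29 newly passed and 17 changed direction. A log2 fold change of at least 1 leaves FOS, ZASP, SULT1A4, GPX2, P2RY11, TP53TG3B, FABP6, ABCF2-H2BE1 and KRTAP2-3. Apart from that minimum, FOS, ZASP, PNRC1, NPPB, FGF1, F3, HSD17B6, IL24 and EDN1 lost the call without the filter and in none of the other refits of these genes. Of these, ZASP has an unadjusted DESeq2 p of 0.404 in the authors' deposited table, so its call holds only for limma on FPKM. Where only left-out libraries are named above, other refits also lost the call. In all, the call was lost in 7 of 14 alternatives for ETV5, 6 of 14 for ACTA2 and CHAC1, and 5 of 14 for AKR1C3, CCND1 and BMF. Losses came in 4 of 14 for MDK, 3 of 14 for CCN2, 4 of 13 for FABP6 and ABCF2-H2BE1, and 3 of 13 for TBC1D3C and TMED7-TICAM2. The changes of direction belong to genes that were not called and to 2 lists; the cause was not tested. With equal totals PPARG had a log2 fold change of -0.0076. Leaving out a library gave log2 fold changes of -0.0045 to 0.43 for RPL38, -0.0024 to 0.24 for RPL23, -1.02 to 0.043 for CD3D, -0.32 to 0.062 for CLDN4, -0.11 to 0.62 for ESAM, -0.21 to 0.20 for ACAN, -0.13 to 0.046 for MMP1, -0.098 to 0.021 for MMP3, -0.27 to 0.016 for CD36, -0.045 to 0.12 for PPARG and -0.26 to 0.11 for FABP5. It gave medians of -0.22 to 0.068 for the fibroblast-like matrix list and -0.088 to 0.0032 for the TGF-beta list. A library left alone in its condition is assumed to vary like the other condition. Alternatives that had been chosen for counts (other count normalizations, another count test and a weighted log-count fit) were not run, since the values are FPKM. Depth limits genes near 1 FPKM, such as FABP4, GPX2 and FABP6.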

Other observations

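The genes of the next sentences and the tests of the 3 patterns below were chosen after the main results were seen, and what each test should show was written before its value was computed. FGF5, a fibroblast growth factor gene, fell to 2.2 ± 0.0141 against 4.20 ± 0.460 FPKM (log2 fold change -0.70, limma adjusted p = 0.0222), the neuregulin gene NRG1 to 15.8 ± 0.00707 against 25.4 ± 4.69 FPKM (log2 fold change -0.63, limma adjusted p = 0.0310) and RGS4, a regulator of G-protein signalling, to 38.9 ± 0.0707 against 58.3 ± 4.89 FPKM (log2 fold change -0.57, limma adjusted p = 0.0367). The adhesion receptor gene ADGRG1 fell to 13.2 ± 0.156 against 21.0 ± 0.629 FPKM (log2 fold change -0.64, limma adjusted p = 0.0148) and the calponin gene CNN1 to 7.44 ± 0.721 against 12.8 ± 1.18 FPKM (log2 fold change -0.71, limma adjusted p = 0.0140). DHRS2, a short-chain dehydrogenase gene, rose to 78.0 ± 5.95 against 47.2 ± 1.99 FPKM (log2 fold change 0.71, limma adjusted p = 0.0129) and the pseudokinase gene TRIB2 to 18.04 ± 0.0778 against 11.6 ± 0.792 FPKM (log2 fold change 0.59, limma adjusted p = 0.0253). FOSB, a relative of FOS, was too low to be tested, at 0.995 ± 0.219 against 0.170 ± 0.0566 FPKM, and has a q of 0.00371 in the authors' deposited table.

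Genes of secretory epithelia stood highest in FABP4 replicate 2: ALDH1A1 had 3.64 FPKM there against at most 0.54 in the other libraries, and LCN2 5.54 against at most 0.75. LCN2 is also a member of the NF-kB list, so it does not point to a cell type alone. A candidate explanation is RNA of an epithelial cell type in that library: of 29 further markers 21 reached 0.1 FPKM, and FABP4 replicate 2 was highest for 13, more than in 99.59% of 10000 random gene sets of like level (median 6). FABP4 replicate 1 was highest for 3, DMSO replicate 1 for 2 and DMSO replicate 2 for 3. Several of the 13 were low even there, such as TFF3 at 0.11 and CP at 0.45 FPKM, and so rest on few fragments. The line expresses part of the list itself, with 8 of the 21 at 1 FPKM or more in both DMSO libraries, and of the abundant ones MUC1 was highest there at 45.72 FPKM against 31.23 to 39.21, while SPINK1 was lowest at 17.95 against 18.98 to 24.76. A response to FABP4 in both replicates stays open, since the markers' median log2 ratio to DMSO in replicate 1 was 0.0882 times that in replicate 2, with a bootstrap range of -0.328 to 1.17. The calls of AKR1C2 and AKR1C3 were lost without FABP4 replicate 2, as they were without DMSO replicate 2. Their log2 fold changes were 0.55 and 0.54 without FABP4 replicate 2, and 0.75 and 0.91 without DMSO replicate 2. GPX2 and MDK, also highest in FABP4 replicate 2, stayed higher without it, with log2 fold changes of 0.79 and 0.64 against 1.60 and 0.94 with all libraries.

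The lower levels of CCN2, F3, ACTG2, CNN1 and ACTA2 led to the hypothesis that targets of YAP and TEAD and of MRTF and SRF, transcription factors that respond to the actin cytoskeleton, are lower as sets. Of targets not looked at before, 15 of 18 YAP and TEAD targets lay below 0 (median log2 fold change -0.12; as low in 0.08% of 10000 random sets of like level), and 22 of 23 MRTF and SRF targets (median -0.22; as low in 0%). None of these 41 genes passed singly in limma, with 5 and 6 at an unadjusted p under 0.05 and 2 and 0 at a q under 0.05 in the authors' deposited table. Over both sets the median was -0.22 under median-of-ratios scaling and -0.19 under quantile normalization, as low in 0% of random sets. Rescaling moves the random sets too, from a range of -0.049 to 0.039 to one of -0.067 to 0.021 under median-of-ratios scaling. The rescaled values are thus no further test. A scaling that acts by library or by level would shift genes of like level together, so the place below random sets argues against that. The sets were matched on level alone, so a technical difference that follows other properties of the transcripts stays untested. Between libraries the median for MRTF and SRF targets was -0.27 to -0.16 across conditions against -0.010 and -0.0056 between replicates. For YAP and TEAD targets it was -0.17 to -0.066 against -0.033 and -0.082, so their shift is not clear of the replicate spread. Lower activity of MRTF and SRF with FABP4 may account for the lower level of these cytoskeleton targets, but random sets ignore that such genes move together. The set was chosen among actin cytoskeleton genes and leaves out the immediate early genes, where FOS rose. It therefore does not speak for all SRF targets. Cell density, variation between cultures and the vehicle stay open and untested.

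Multi-copy genes stood out among the calls, with CT47A2 called higher and CT47A5 of the same family called lower. Of the called genes with a transcript 12 of 68 (17.6%) shared at least 50% of their windows with another gene, against 4.56% of 12316 other tested genes (Fisher's exact test, two-sided, p = 5.81e-05). This describes the calls in which such genes had been noticed and does not test the cause, so whether reads shared between near-identical genes contribute to the calls stays open. Summed over the family, the level was 113 ± 15.7 against 104 ± 8.55 FPKM for 12 CT47A genes and 19.2 ± 3.33 against 19.0 ± 2.12 FPKM for P2RY11 and its readthrough (log2 ratios of means 0.11 and 0.014). The means of the other 5 sums had the direction of the called gene, by smaller amounts. The log2 ratios of means were 0.71 for 6 TP53TG3 genes, 0.29 for SULT1A3 and SULT1A4 and 0.27 for 12 TBC1D3 genes. They were -0.24 for TMED7 and its readthrough and -0.16 for ABCF2 and its readthrough. The libraries overlapped between conditions for TBC1D3 (48.43 and 59.98 against 48.89 and 40.98 FPKM) and TMED7 (29.12 and 25 against 28.77 and 35.08 FPKM). They did not overlap for TP53TG3, for SULT1A3 and SULT1A4 or for ABCF2. None of the sums was tested.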
